A study of Mus musculus with 16 samples.

How the data were processed

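The series measured trimethylation and acetylation of lysine 9 of histone H3 (H3K9me3, a mark of silenced chromatin, and H3K9ac, a mark of active gene starts) by chromatin immunoprecipitation and sequencing in naive CD4 T cells of mice. Cells of wild-type (WT) littermates were compared with knockout (KO) cells lacking TRIM28, an adaptor protein that zinc finger proteins recruit to silence chromatin. The 16 libraries fell into 8 groups of 2, made of each genotype's H3K9me3, H3K9ac and 2 kinds of input, the second of which was labelled as belonging to H3K9ac.

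The 4 lists used here hold islands, which are enriched stretches of the genome, 1 list per mark and genotype. Reads were aligned with Bowtie2 to mm10, handled with SAMtools and searched for islands with SICER 1.1, per the submitters' processing notes, and read filters are not given in the sources used here. The deposited lists were called on the 2 merged replicates of a group, so each list stands for 1 pooled library per group. The authors' deposited read counts per island, 1 for the pooled ChIP and 1 for the pooled input, were not normalized. The deposited p-value of each island is a Poisson probability of the ChIP reads given scaled input reads, and the deposited FDR reached at most 0.05. The deposited fold of each island is the ratio of ChIP reads to input reads scaled by library size, and it is the authors' own value. In every island with input reads, both formulas gave the deposited fold and p-value back, within a relative difference of 1e-09 for the fold and 1e-06 for the p-value. A single WT H3K9ac island had 0 input reads. Island lengths were multiples of 500 bp, and positions are printed counting from 1. Which input went with which list is not given in the sources used here and was taken from the library titles.

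Total depth is not given in the sources used here. The ChIP library was 0.664 times the size of its input in WT and 0.693 times in KO for H3K9me3, and 0.822 and 0.945 times for H3K9ac. Input reads per kb in matched autosomal islands put the depth of the KO ChIP at 1.04 times WT for H3K9me3 and 1.08 times WT for H3K9ac. The median island held 755 ChIP reads in WT and 954 in KO for H3K9me3, and 461 and 509 for H3K9ac. Intervals of matched pairs cover counting error only. Bootstrap intervals resample islands and cover the spread between them. Exact intervals of a percentage treat islands as independent. None of these intervals covers differences between animals or replicates.

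The following choices were made before the data were examined. An island was specific to a genotype when no island of the other genotype and the same mark overlapped it or lay within 1500 bp. Islands of both genotypes were matched when they overlapped each other by at least 50% of both lengths, overlapped no other island, and held at least 50 ChIP and 10 input reads. The log2 ratio of KO over WT enrichment was centred on its median, and a pair was called at 2-fold or more when its exact conditional binomial 95% interval excluded no change. Overlap between marks was set against 1000 circular shifts along each chromosome. A gene carried H3K9me3 when an island lay within 2 kb of its body. The difference between WT-specific-only and KO-specific-only members of 19 gene lists was placed among 10000 random lists matched on deciles of gene length. The list called genes named Zfp here also admitted Zkscan, Zscan and a few other zinc finger gene names. For H3K9ac the plan was a window of 1 kb around the gene start. The annotation used here (GRCm38.p6, the assembly of mm10) gave no strand, so a window of 1 kb around either annotated gene end was used. Named genes were Trim28, the 10 protein-coding genes per mark and genotype with the specific island of most excess ChIP reads (gene models named Gm plus a number or ending in Rik left out), up to 4 members per list by the same measure or, without a specific island, up to 2 by ChIP reads, the 5 matched pairs with the largest change in each direction, and the 3 specific islands with most excess reads.

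Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. The comparisons were tested on simulated data: all 200 removed islands were called specific for H3K9me3 among 38539 islands and for H3K9ac among 26352, and all 4-fold changes of 200 pairs were called for both marks. Of unchanged simulated pairs, 0.00262% were called for H3K9me3 and 0.0231% for H3K9ac. The removed islands had no neighbour within 1500 bp, and all other islands kept identical boundaries. These rates therefore check the calculation and counting error only, and cannot show how often unequal island boundaries produce a call. Alternatives were stricter FDR limits, a 2-fold minimum, other definitions of a shared island, autosomes alone, the KO ChIP thinned to the WT depth with inputs left as they were, longer islands, other matching and scaling, and other gene windows. The comparison of islands of at least 2-fold with the full list of the other genotype was chosen after seeing the data. Repeats, exons and introns were not analysed here. A locus picked by the rule for named genes, with the genes sharing its island, is not reported here.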

Results

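H3K9me3 and H3K9ac were profiled in WT and Trim28 KO naive CD4 T cells of mice to ask how an adaptor of gene silencing shapes both marks. The H3K9me3 list held 38539 islands covering 706.6 Mb in WT and 30843 islands covering 738.1 Mb in KO. The H3K9ac list held 26352 islands covering 187.3 Mb in WT and 21245 covering 142.4 Mb in KO. Replicates were merged before islands were called, so no difference below has a replicate check, and each compares 1 pooled library with another.

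Trim28 (gene 21849, chromosome 7, 13024152 to 13031032) carried no H3K9me3 island in either genotype. An H3K9ac island lay at its end in WT (13023001 to 13025500, fold 3.07) and in KO (13023001 to 13026000, fold 2.56). The deleted part of the gene is not resolved by these islands, so they check nothing about the genotype labels.

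H3K9me3 islands at zinc finger genes and at short, strongly enriched sites were fewer in the KO list than in the WT list. WT had 8143 islands without a KO counterpart and KO had 4355 without a WT counterpart. The WT-specific islands had a median fold of 1.66 and a median length of 5 kb, and the KO-specific ones 1.28 and 9 kb. A 26 kb island over Zfp382 and Zfp146, zinc finger genes of chromosome 7 (30137501 to 30163500), held 2560 ChIP reads at fold 2.22 in WT and had no KO counterpart. Islands over Zfp780b (chromosome 7, 27947501 to 27973000, fold 1.98) and Zfp445 (chromosome 9, 122848001 to 122863000, fold 2.31) were also listed in WT alone. So was an island ending within 2 kb of Resf1, which encodes a regulator of retroelement silencing (chromosome 6, 149275001 to 149308500, fold 1.77). KO had an island inside Resf1 (149323001 to 149329500, fold 2.10), with a WT island within 1500 bp of it. An island 35.5 kb long on chromosome 10 (83424001 to 83459500, fold 2.15) overlapped no gene and lay 27.9 kb from Aldh1l2.

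The islands with most excess reads in KO alone were broad and weak. They lay over or within 2 kb of the genes Thsd7a (chromosome 6, 12400001 to 12448500, fold 1.28), Sgcd (fold 1.29), Sema3c (fold 1.24), Dgkb (fold 1.27), Anks1b (fold 1.60) and Magi2 (fold 1.27), and of the olfactory receptor genes Olfr976 (fold 1.31), Olfr982, Olfr983 and Olfr984 (fold 1.36). The other 2 leading KO islands overlapped no gene, on chromosome 14 (98496001 to 98531000, fold 1.33) and chromosome 4 (97230501 to 97261000, fold 1.39).

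The difference was widest among strongly enriched islands, a comparison chosen after seeing the data. WT had 2870 H3K9me3 islands of at least 2-fold and KO had 273. Of the WT ones, 2272 (79.2%) had no KO island within 1500 bp, whereas 23 of the 273 KO ones had no WT island. At 3-fold the numbers were 361 and 10. These 2272 islands had a median length of 2.5 kb. Of them, 55 (2.42%) lay at a gene of the list of genes named Zfp, against 288 (0.747%) of all WT islands.

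**Figure D1:**
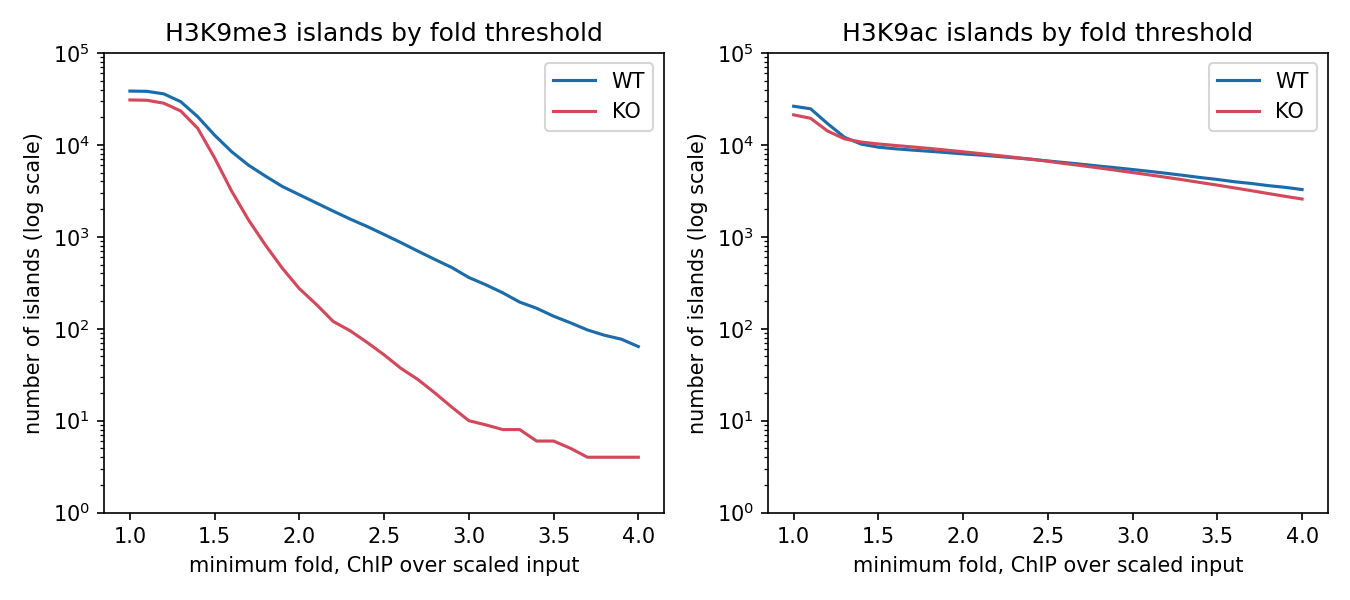
Number of islands (vertical axis, log scale) with at least the fold on the horizontal axis, for H3K9me3 on the left and H3K9ac on the right, with WT in blue and KO in red. For H3K9me3 the curves part to 2870 WT and 273 KO islands at 2-fold, and for H3K9ac they stand at 7991 and 8419.

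Around Zfp445 on chromosome 9, WT had H3K9me3 islands at 122848001 to 122863000 (fold 2.31), 122866501 to 122877500 (fold 1.93) and 122879501 to 122884000 (fold 2.80). KO had a single shorter island within the gene, at 122881001 to 122883000, with fold 1.77. An H3K9ac island inside the gene (122865001 to 122866000 in WT) had fold 7.39 in WT and 2.69 in KO. An island at the gene end (122886501 to 122887500 in WT) had 5.96 and 2.18. Both were 1 kb long in WT and 2.5 kb in KO. ChIP reads were 249 in WT and 387 in KO at the first, and 240 and 317 at the second. Input reads were 41 and 152, and 49 and 154, so the lower KO fold does not show fewer H3K9ac reads. The surroundings of Zfp445 were chosen for display after their values were seen.

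**Figure D2:**
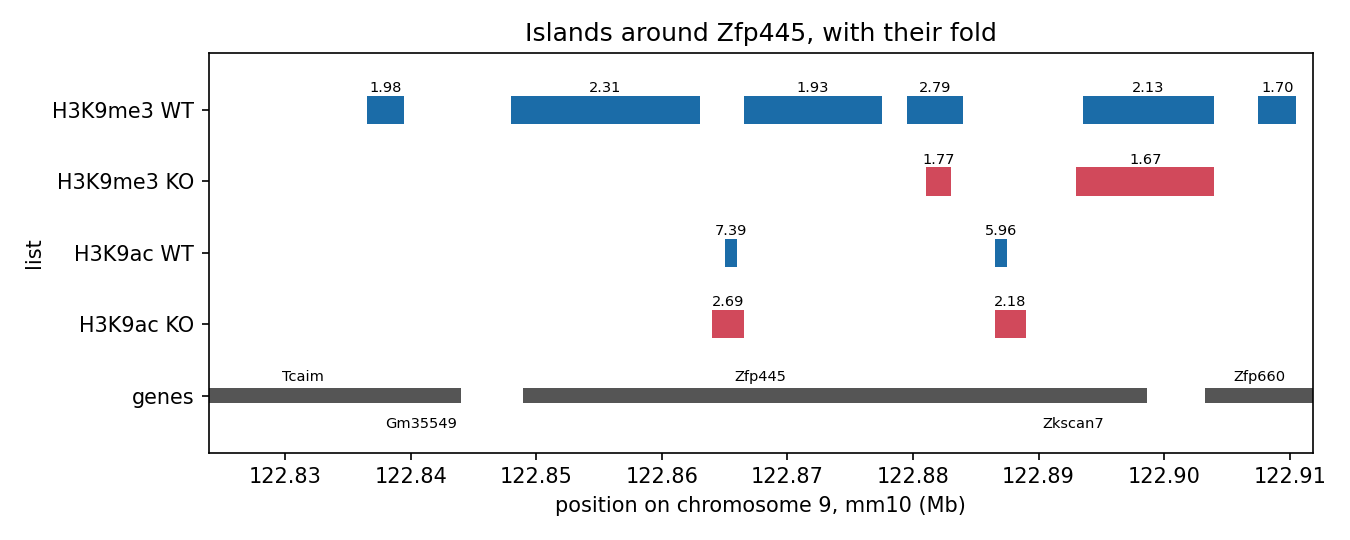
Map of islands (bars, with the deposited fold above each) and genes along chromosome 9 in mm10 (horizontal axis, Mb), with a line per mark and genotype, WT in blue and KO in red. The WT H3K9me3 islands of fold 2.31 and 1.93 over Zfp445 have no KO counterpart.

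Of 425 zinc finger genes named Zfp, 103 had a WT-specific H3K9me3 island only and 3 a KO-specific one only, and 0% of random lists matched on gene length gave as large a difference. The 103 members lay at 112 WT-specific islands. Clustered protocadherins, adhesion genes of neurons, had 18 of 57 against 0, but these 18 shared 2 islands, and Pcdhga1, Pcdhga2, Pcdhga3 and Pcdhgb1 shared that of fold 2.65. Hox genes, which pattern the body axis, had 10 of 39 against 0 at 5 islands, among them Hoxa3, Hoxa5 and Hoxa6 (fold 2.32) and Hoxd11 (fold 1.70). Random lists draw scattered genes, so for these neighbouring genes the whole list was instead shifted along the gene order, without matching on length, a test chosen after seeing the data. A difference as large was found in 0% of shifts for genes named Zfp, 0.315% for protocadherins and 1.90% for Hox genes. At 2-fold Hox genes had 3 against 0 (5.15% of random lists as large). The protocadherin difference was ordinary when islands within 2.5 kb of gene ends were counted, at the mid-percentile 54.2.

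Interferon-stimulated genes had a WT-specific island only in 6 of 37 members and a KO-specific one in 0, and 6.01% of random lists and 14.1% of shifts gave as large a difference. They included Oasl2 (fold 3.30), Usp18 (fold 2.70), Mndal (fold 2.64) and Rtp4 (fold 1.93). Imprinted genes had 9 of 46 against 2, within the range of random lists (27.1% as large), with Airn (fold 1.75), Mest (fold 2.04), and Gnas and Gnasas1 (fold 2.17). Germline genes had 7 of 30 against 2 (33.2% as large), with Tdrd9 (fold 4.03) and Mov10l1 (fold 3.19), members of the pathway of small RNAs against transposons, and Sycp2 in KO (fold 1.31). Genes of the H3K9 methylation machinery had 3 of 26 against 0 (58.1% as large), namely Resf1, Atf7ip (fold 2.91) and Chd4 (fold 1.95).

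T cell identity genes had a WT-specific island only in 4 of 30 members and a KO-specific one in 0 (47.7% of random lists as large). These were Foxp1 (fold 2.71), Zap70 (fold 2.28), Il7r (fold 1.499) and Themis (fold 1.29). T helper lineage genes had 1 of 32 against 0 (81.2% as large). Activation and checkpoint genes had 1 of 22 each way (93.7% as large), Tox in WT (fold 2.07) and Nr4a2 in KO (fold 1.27). CD8 T and NK cell markers had 3 of 15 against 0 (4.88% as large, and 18.3% of shifts), Klrb1c (fold 2.33), Klra7 (fold 1.4997) and Klrc1 (fold 1.32). Myeloid markers had 1 of 15 against 0 (53.1% as large), Fcgr3 (fold 2.13), B cell markers 1 of 12 each way (90.5% as large), Pax5 in WT (fold 1.74) and Cr2 in KO (fold 1.18), and erythroid markers 0 of 10.

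Of 1106 olfactory receptor genes, 30 had a WT-specific H3K9me3 island only and 82 a KO-specific one only, and 0% of random lists lay as low. At 2-fold they had 1 and 0. Vomeronasal receptor genes had 15 and 18 of 353 (1.32% of random lists as low), 2 and 0 at 2-fold, and the mid-percentile 16.5 when islands within 2.5 kb of gene ends were counted, with Vmn2r97 in WT (fold 2.05) and Vmn2r58 (fold 1.82), Vmn2r82 (fold 1.43) and Vmn1r7 (fold 1.22) in KO. Killer cell lectin-like, serpin and Tdpoz cluster genes had 7 and 3 of 89 (71.7% of random lists as large), with Klrb1a (fold 1.83), Klrg2 (fold 1.64) and Serpinb9 (fold 1.37) in WT. Ribosomal protein genes had 0 of 83, with shared islands at Rpl10l and Rpl39l, and histone genes had 0 of 67 and no H3K9me3 island at all. Over all 21883 protein-coding genes, 2391 had a WT-specific island only and 584 a KO-specific one only.

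**Figure D3:**
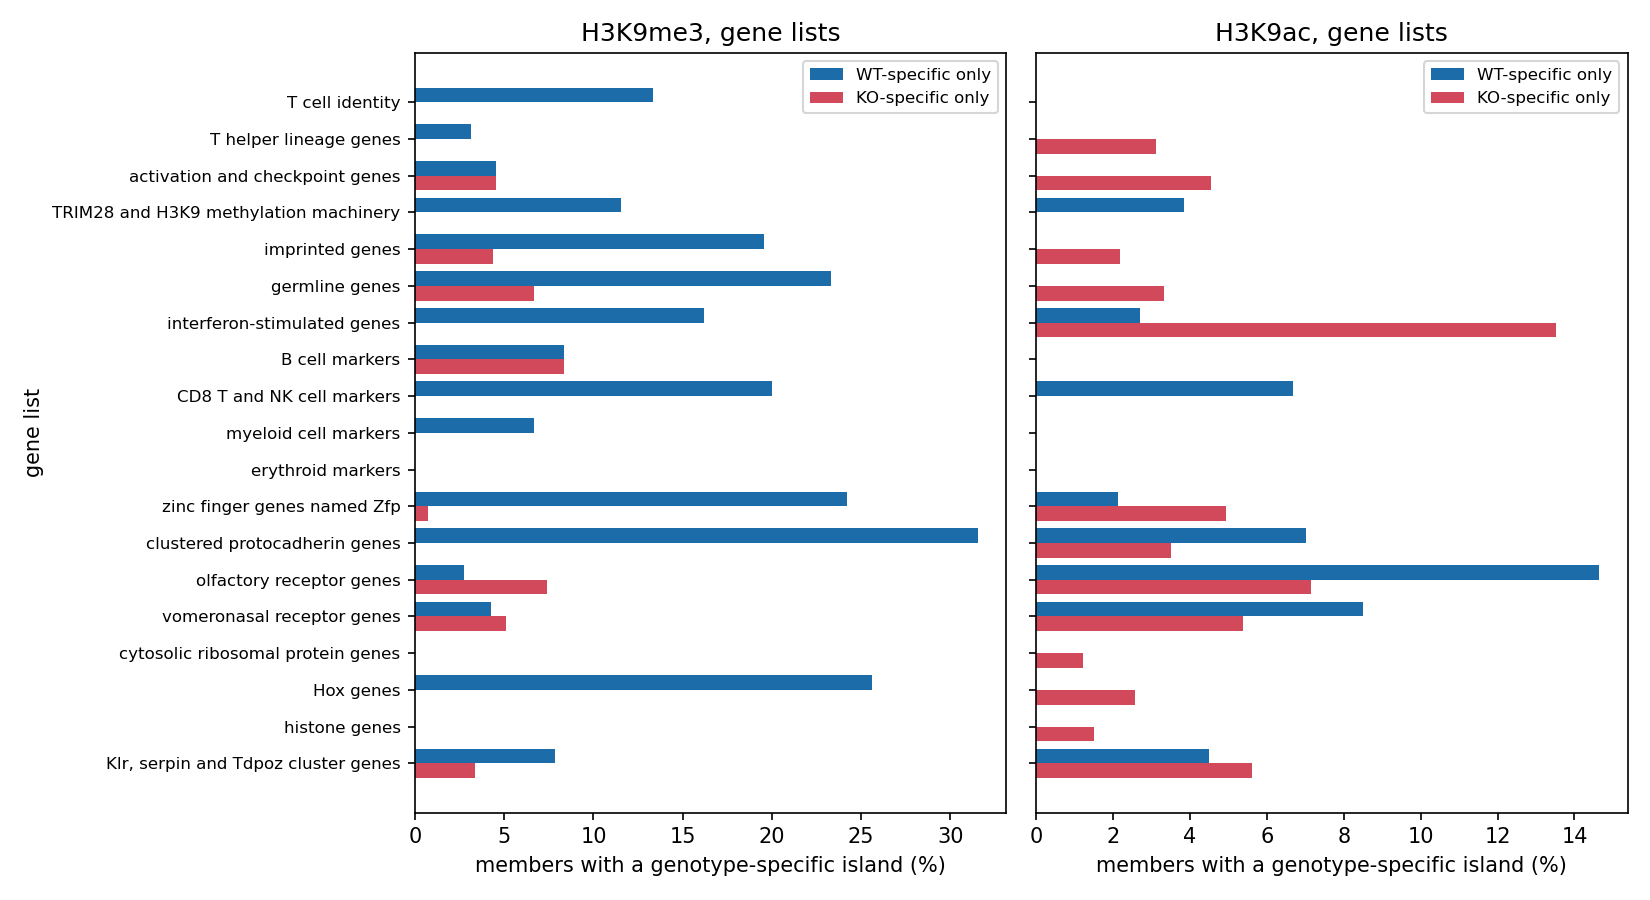
Percent of the members of each of 19 gene lists (vertical axis) with a genotype-specific island (horizontal axis), WT only in blue and KO only in red, for H3K9me3 on the left and H3K9ac on the right. For H3K9me3, 103 of 425 genes named Zfp are WT only and 3 are KO only, and 82 of 1106 olfactory receptor genes are KO only.

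Few matched H3K9me3 pairs changed 2-fold. A pair needs an island listed in both genotypes, so a weak WT island that halved in KO could leave no pair. Of 9164 matched pairs, 17 were called lower and 1 higher in KO, around a median log2 ratio of 0.01. The lowest was on chromosome 11 (61605001 to 61610500), where fold was 6.16 in WT and 1.92 in KO (centred log2 -1.69, interval -1.84 to -1.55), overlapping no annotated gene. Pkp4 (log2 -1.20), the U1 small nuclear RNA gene Rnu1b1 (log2 -1.18), Zfp958 (log2 -1.15) and a gene model on chromosome 4 (126663501 to 126671000, log2 -1.21) followed. The called higher pair was on chromosome 7 (22820501 to 22822500 in WT and 22820501 to 22821500 in KO, log2 1.08, interval 0.73 to 1.43), with 168 ChIP and 129 input reads in WT and 119 and 41 in KO. The pairs next in size lay at Bmp3 (log2 0.67), Zfp980 (log2 0.64), a site on chromosome 3 (70059001 to 70064000, log2 0.64) and Alk (log2 0.60), none of them called. Pairs with a mean fold of 2 to 4 had a median log2 ratio of -0.35 (206 pairs), and 80.6% of them were lower in KO. Pairs with a mean fold under 1.5 had 0.03 (6597 pairs), and 41.5% of them were lower. The median folds of these weak pairs were 1.35 in WT and 1.37 in KO.

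Chromosome X stood apart for H3K9me3. It had 1918 islands in WT and 718 in KO, and the covered length was 23.7 Mb and 7.40 Mb, whereas autosomes had 36619 and 30122 islands. Xist, the RNA gene that silences 1 X chromosome in female cells, had an H3K9ac island in WT alone (chromosome X, 103481001 to 103483500, fold 3.87). The Y-linked genes Ddx3y (fold 15.7), Uty (fold 10.5), Eif2s3y (fold 11.7) and Kdm5d (fold 14.4) had H3K9ac islands in KO alone. Xist, Eif2s3y and Kdm5d were chosen after their values were seen. On autosomes alone, 6880 WT-specific and 4289 KO-specific H3K9me3 islands were listed, and 2225 and 23 of at least 2-fold.

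**Figure D4:**
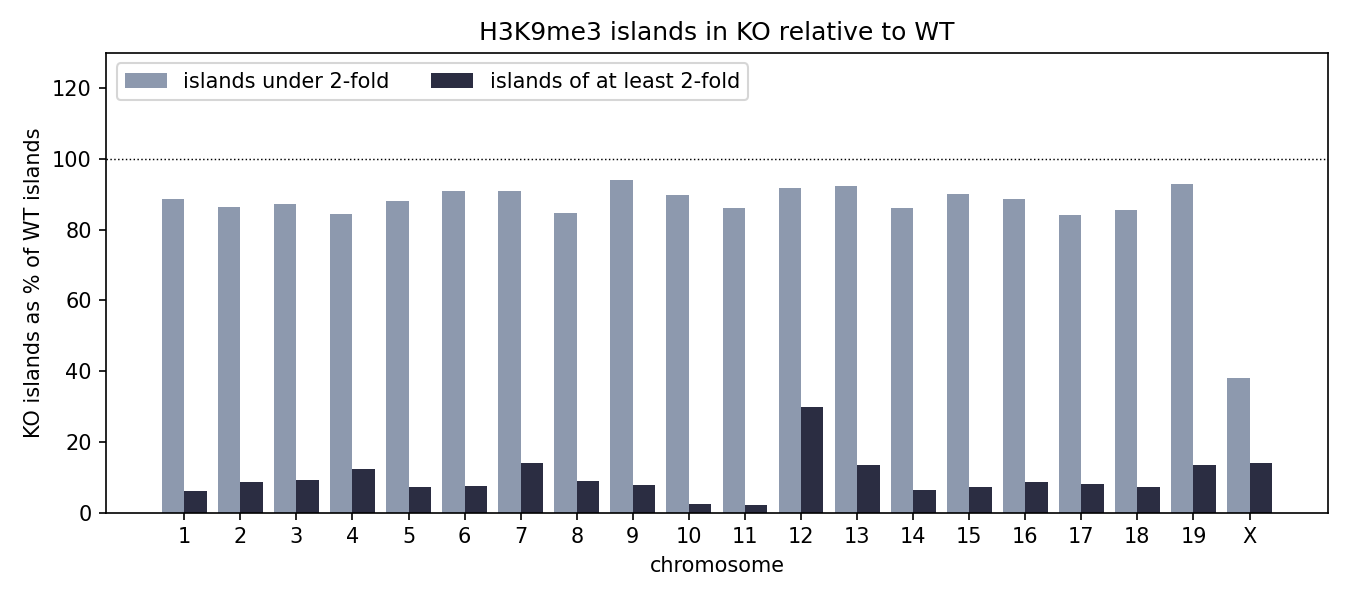
Number of KO H3K9me3 islands as a percent of WT islands (vertical axis) per chromosome (horizontal axis), for islands under 2-fold in grey and of at least 2-fold in dark blue, with a dotted line at 100%. On X the islands under 2-fold stand at 38.2% and those of at least 2-fold at 14.0%, against 88.3% and 9.42% over all autosomes.

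H3K9ac islands specific to a genotype were mostly weak, and 5.69% of them in WT and 10.7% in KO lay at an end of a protein-coding gene. WT had 11741 without a KO counterpart and KO had 6936, with median folds of 1.19 and 1.20, and shared islands had 2.24 and 2.23. At 2-fold the order turned: 107 WT and 582 KO islands had no counterpart in the full other list, a comparison chosen after seeing the data, and 994 and 1454 when both lists were limited to 2-fold. Of the 107 and 582, 68 (63.6%) and 247 (42.4%) lay at a gene end. The WT-specific island with the most excess reads lay at Trbv21 in the T cell receptor beta locus (chromosome 6, 41196501 to 41203000, fold 7.74), where input was sparse, at 15.2 reads per kb against a median of 60.5 in autosomal islands of that list. KO-specific islands of fold 1.11 (40957001 to 40964000) and 1.84 (41080501 to 41083000) lay in the same locus and were chosen after their values were seen. The leading KO-specific ones lay on chromosome 18 (82239501 to 82249000, fold 2.61), at Fam241a (chromosome 3, 127871501 to 127882000, fold 2.20) and on chromosome 12 (99640001 to 99650000, fold 2.23). The other leading WT islands were weak, over Agmo (fold 1.25) and on chromosome 16 (54010501 to 54048000, fold 1.19).

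At gene ends, KO-specific H3K9ac was found at Ifi209, an interferon-inducible gene (chromosome 1, 173630501 to 173635000, fold 2.68), Cyp2s1 (fold 2.55), Ccdc102a (fold 4.49), Plin3 (fold 2.09), Ly6a, which encodes the surface protein Sca-1 (fold 1.94), Scd2 (fold 1.79), Ddx3y and Uty, and at Nyx (fold 1.85) and Gpr34 (fold 1.88) on chromosome X. The leading WT-specific islands at gene ends had folds of 1.41 or less, at Slco1a1 (fold 1.41), Cyp4a14 (fold 1.34), Olfr354 (fold 1.29), Slco6d1 (fold 1.28), Toporsl (fold 1.27), Kcnj3 (fold 1.25), Cnrip1 (fold 1.23), Dsc3 (fold 1.20), Slc13a1 (fold 1.15) and Zfp982 (fold 1.08). Over all protein-coding genes, 697 had a WT-specific island only and 798 a KO-specific one only, and 82 and 285 at 2-fold.

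T cell identity genes carried H3K9ac in both genotypes. Of 30, 28 had an island at a gene end in each and 0 had a specific one. Satb1, a chromatin organiser of T cells, had fold 3.82 in WT and 3.12 in KO. Cd4 had fold 3.08 in WT and 2.07 in KO, with 69.7 input reads per kb in WT and 287 in KO. Its ChIP reads were 1589 over 9 kb in WT and 5889 over 10.5 kb in KO, so the lower fold does not show fewer H3K9ac reads. The KO input density there was 5.02 times the autosomal median of that list, so the ChIP reads do not show more H3K9ac either. Interferon-stimulated genes had a KO-specific island only in 5 of 37 members and a WT-specific one only in 1, and 2.28% of random lists lay as low. Dhx58 (fold 1.99), Oas2 (fold 1.65) and Oasl2 (fold 1.60) were KO-specific and Ifi204 (fold 1.20) was WT-specific. Ifi44 (fold 1.47) and Ifit3b (fold 1.08) made up the rest, chosen after their values were seen. None of these was at 2-fold, and the list's mid-percentile was then 64.6, and 5.49 with FDR at most 0.001, so the difference depended on these settings.

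In H3K9ac, T helper genes had 0 WT-specific-only and 1 KO-specific-only member of 32 (Cxcr5, fold 1.16), activation genes 0 and 1 of 22 (Lag3, fold 1.34), and the methylation machinery 1 and 0 of 26 (Suv39h1 on chromosome X, fold 2.38). Imprinted genes had 0 and 1 of 46 (Zdbf2, fold 1.13), germline genes 0 and 1 of 30 (Ddx4, fold 1.08), CD8 T and NK markers 1 and 0 of 15 (Klra4, fold 1.23) and Hox genes 0 and 1 of 39 (Hoxa4, fold 3.50). B cell markers (12), myeloid markers (15) and erythroid markers (10) had 0 specific islands, with shared ones at Cd79a, Cd68, Spi1 and Klf1. Genes named Zfp had 9 and 21 of 425 (11.99% of random lists as low), with Zfp870 (fold 2.60) and Zfp608 (fold 1.62) in KO and Zfp981 (fold 1.05) in WT. With FDR at most 0.001 the mid-percentile of genes named Zfp was 0.075, and that of histone genes 0.975. Genes named Zfp stood at 58.95 at 2-fold, with 2 and 6 members, and at 14.1 within 2.5 kb of gene ends. Protocadherins had 4 and 2 of 57, with Pcdhb2 (fold 1.26) and Pcdhb1 (fold 1.14) in WT and Pcdhb11 (fold 1.22) and Pcdha2 (fold 1.18) in KO. Ribosomal protein genes had 0 and 1 of 83 (Rpl3l, fold 2.17), histone genes 0 and 1 of 67 (H3c6, fold 2.87), vomeronasal receptors 30 and 19 of 353, and the lectin-like, serpin and Tdpoz clusters 4 and 5 of 89. Olfactory receptor genes had 162 WT-specific-only and 79 KO-specific-only members of 1106, and 0% of random lists gave as large a difference, with folds of 1.29 or less at Olfr354, Olfr1212, Olfr1014 and Olfr1015. At 2-fold they had 0 and 1, at the mid-percentile 76.9.

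In matched H3K9ac islands, 111 of 9326 pairs were called higher and 115 lower in KO, around a median log2 ratio of -0.02. The lowest lay at Hdac5 (log2 -1.87), Fxr1 (log2 -1.82), Ndufc1 (log2 -1.81), the histone gene H3f3b (log2 -1.67) and Zfp747 (log2 -1.62). The highest lay at Erbb2 and Mien1 (log2 1.91), Psme3 (log2 1.70), Helz (log2 1.70), Dnal4 (log2 1.68) and Tmem243 (log2 1.58). The compared islands differed in length: the KO island was longer in 108 of the 115 lower pairs and shorter in 81 of the 111 higher ones, a count made after seeing the data. At Hdac5 the ChIP reads were 224 in WT and 268 in KO, and the input reads 20 and 77, and at Psme3 540 and 515, and 198 and 51. With ChIP reads per kb and no input, 13 of the 111 and 4 of the 115 were still called. The median log2 ratios of the 111 and 115 pairs went from 1.14 to 0.67 and from -1.17 to -0.68, under the 2-fold limit. Reads per kb still divide by each island's own length, so this scaling gives no separate support for the direction.

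H3K9ac and H3K9me3 islands of the same genotype shared 109.8 Mb in WT and 76.5 Mb in KO, 2.04 and 1.77 times the mean of the shifts. This lay in weak islands: H3K9ac islands of at least 2-fold, a limit chosen after seeing the data, shared 0.0205 Mb in WT and 0.0105 Mb in KO, against 5.54 and 7.29 Mb for the shifts. With FDR at most 1e-05 in both lists, the log2 ratio over shifts went from 0.82 to 0.079 in KO and from 1.03 to 0.70 in WT.

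H3K9ac specific to either genotype lay less often than in the shifts where H3K9me3 was listed in WT alone. Of 6936 KO-specific H3K9ac islands, 139 lay at a WT-specific H3K9me3 island, against a mean of 309.6 over the shifts. The WT-specific H3K9ac islands at WT-specific H3K9me3 numbered 203 (mean of shifts 545), those of WT at KO-specific H3K9me3 729 (431.6) and those of KO at KO-specific H3K9me3 335 (243.5). At WT-specific H3K9me3 the ratio to the shifts was 0.449 for KO-specific and 0.373 for WT-specific H3K9ac. Both fell short there, so the shortfall cannot decide whether H3K9ac appears where H3K9me3 is lost. At 2-fold, 6 KO-specific H3K9ac islands lay at WT-specific H3K9me3 islands (mean of shifts 4.18, range 1 to 9 over the central 95%, and 256 of 1000 shifts as large), by Zfp870, Tanc2, Zcchc3, Iffo2, Rgs9bp with Ankrd27, and a site on chromosome 1 (13513501 to 13514500). These 6 sites were chosen after their values were seen.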

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

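All tests in this part were chosen after the results were seen. KO had 4 H3K9ac islands on the Y chromosome and WT had 0, at Ddx3y, Uty, Eif2s3y and Kdm5d. H3K9me3 islands on Y numbered 2 in WT and 3 in KO. Their input density was 232 and 253 reads per kb, against 70.2 in the autosomal islands of either list. Islands so dense in input do not show that the WT pool held a Y chromosome. H3K9ac was listed at these Y-linked genes in KO alone (folds 10.5 to 15.7) and at Xist in WT alone (fold 3.87). The KO pool thus held cells with a Y chromosome, and the pools differed in sex make-up. Sex is therefore mixed with genotype in every comparison of WT with KO. X-linked H3K9me3 islands numbered 1918 in WT and 718 in KO. Whether fewer X copies in the KO pool account for this remains open. Input density of 90 matched X islands, relative to autosomal ones, was 0.931 of WT (bootstrap interval 0.917 to 0.941). In the separate inputs of 113 matched X islands of H3K9ac it was 0.9685 (0.928 to 0.9997). H3K9ac islands on X numbered 256 in WT and 264 in KO. Among islands of at least 2-fold, KO ones on X were 14.0% of WT (exact interval 5.78 to 29.6%), against 9.42% on autosomes. X stood apart in islands under 2-fold, with 1861 in WT and 710 in KO (38.2%, against 88.3% on autosomes). The 2-fold comparison therefore does not bear on the X difference. A stronger effect of TRIM28 loss on X was not tested in the weak islands. It cannot be told apart from sex make-up in 1 pool per genotype.

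Input reads were unusually dense in a single list at Cd4 in the KO H3K9ac list (chromosome 6, 124878501 to 124889000, 287 reads per kb). The same was seen on chromosome 2 in the WT H3K9ac list (98662001 to 98667500, 540.4 reads per kb) and on chromosome 17 in the WT H3K9me3 list (13540001 to 13551000, 219.7 reads per kb). The H3K9me3 lists held no island at Cd4, so they give no input count there.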

How the results depend on the processing

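No paired analysis was possible because the replicates were merged before islands were called, and leaving out a replicate was not possible for the same reason. The 2-fold comparisons against the full other list, those on autosomes at 2-fold, those of the marks at 2-fold, and the interval with input error were chosen after seeing the data. WT-specific H3K9me3 islands outnumbered KO-specific ones under every alternative run. With both lists at 2-fold they were 2711 and 116, against the full other list 2272 and 23, and on autosomes 2225 and 23. With 50% of the island length as the rule, KO-specific ones rose to 6862. For H3K9ac, FDR at most 1e-05 left 5812 and 4105, or 4475 and 3091 against the full other list. The order turned at 2-fold, with 994 and 1454 (log2 -0.55) in both lists, 107 and 582 (log2 -2.44) against the full other list and 101 and 558 (log2 -2.47) on autosomes, and the cause was not tested. Matched H3K9me3 islands at 80% overlap gave 0 higher and 7 lower, and ChIP reads per kb or a minimum of 200 ChIP and 20 input reads gave 0 higher. Matched H3K9ac islands gave 25 higher and 10 lower at 80% overlap. They gave 22 and 7 with ChIP reads per kb, where input counts play no part but island lengths do. The log2 overlap of the marks over shifts moved in KO to 0.079 at FDR 1e-05, and turned to -8.08 in WT and -9.44 in KO for H3K9ac islands of at least 2-fold. KO-specific H3K9ac at WT-specific H3K9me3 came to 6 at 2-fold, with the log2 ratio turning to 0.49, within chance, as 256 of 1000 shifts held as many. Protein-coding genes with WT-specific H3K9me3 only were 1203 within 2.5 kb of gene ends and 1144 at 2-fold, where KO-specific ones were 5, and for H3K9ac 82 and 285 at 2-fold. The interferon-stimulated list in H3K9ac turned to the mid-percentile 64.6 at 2-fold and moved to 5.49 at FDR 0.001, where genes named Zfp moved to 0.075 and histone genes to 0.975. Olfactory genes moved to 76.9 at 2-fold. For H3K9me3, Hox genes moved to 97 at 2-fold, and vomeronasal genes to 16.5 and protocadherins to 54.2 within 2.5 kb of gene ends. There CD8 T and NK markers moved from 97.4 to 97.7, but they stood at 72.6 without a flank and 78.1 at 2-fold. Interferon-stimulated genes moved from 95.7 to 98.3 without a flank, but stood at 59.45 within 2.5 kb of gene ends. Shifting lists along the gene order, added after seeing the data, moved ribosomal protein genes to 1.615. Total depth is unknown, so weak islands near the calling limit are the least certain.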

Other observations

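The tests of the H3K9me3 difference in this part were chosen after the result was seen, and the test of H3K9ac at genes was set down before its result. Among interferon-inducible genes of chromosome 1, Ifi213 had WT-specific H3K9me3 islands of fold 2.16 (173562501 to 173567500) and 2.93 (173573001 to 173581500), and Mndal had fold 2.64. H3K9ac at these genes was listed in both genotypes, with fold 3.48 in WT and 3.40 in KO at Mndal, and 2.02 and 1.73 at Ifi213. The KO islands were longer, with 363 ChIP reads over 3 kb against 337 over 2.5 kb at Mndal. At Ifi213 they held 349 over 3.5 kb against 212 over 2 kb. These folds therefore do not show whether H3K9ac changed. H3K9ac was listed in KO alone at Ifi209 (fold 2.68) and in WT alone at Ifi204 (fold 1.20), and these genes were not tested as a group. At Tdrd9, a germline gene of the small RNA pathway on chromosome 12, the WT H3K9me3 island at 112010501 to 112017000 (fold 1.68) lay exactly where KO had an H3K9ac island (fold 2.08). Ifi213 and the sites at Tdrd9 were chosen after their values were seen.

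H3K9me3 islands of at least 2-fold numbered 2870 in WT and 273 in KO. Lower depth is argued against, since the KO ChIP was 1.04 times as deep as WT. Excess over input in 4504 broad, weak matched islands was 1.101 times WT in KO (bootstrap interval 1.091 to 1.114). In 206 pairs with a mean fold of 2 to 4 it was 0.666 times. For islands listed in both genotypes, this argues against a weaker immunoprecipitation as the whole cause. Weak WT islands that fell below the calling limit in KO left no pair, so the ratio does not cover them. Merging into longer KO islands does not account for most of the difference, as 79.2% of the WT islands (exact interval 77.6 to 80.6%) had no KO island nearby. Loss of TRIM28 may underlie the difference, as a hypothesis. With 1 pool per genotype, a difference between the pooled animals remains open, including the difference in sex make-up given above.

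The hypothesis was that H3K9ac appears in KO at genes that lost focal H3K9me3. The predicted excess over random lists was not found. Of 1144 protein-coding genes with a WT-specific H3K9me3 island of at least 2-fold, 43 had a KO-specific H3K9ac island, where random length-matched lists had a mean of 44.7 and 62.3% held as many. A WT-specific H3K9ac island was found at 6 of them, against a mean of 38.2 in random lists. Lists matched on length alone thus did not match these genes in H3K9ac, so the test cannot decide the hypothesis. Among these genes, KO-specific H3K9ac (43) outnumbered WT-specific H3K9ac (6), where random lists had means of 44.7 and 38.2.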
